A study of Drosophila melanogaster with 8 samples.

How the data were processed

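Genomic DNA from Drosophila melanogaster embryos was compared with reference DNA by array comparative genomic hybridization, in which 2 DNA samples carry different dyes and compete for the same spots. Per the labels, each of 8 arrays took DNA of mutant embryos aged 3.5 to 8 hours in Cy5 (red) and DNA of Oregon R embryos aged 0 to 8 hours in Cy3 (green), with no dye swap. DNA was extracted with proteinase K and phenol/chloroform and labelled with a random-priming kit, per the labels' protocols. The array is a custom Agilent design with 105072 spots, of which 103747 are not controls, and its probes are 60 bases long.

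The deposited scanner tables hold linear intensity values for each spot, which Agilent Feature Extraction 9.5.3.1 background-subtracted, spatially detrended and dye-normalized, per the file headers. The headers give a linear dye factor per channel and a lowess term of 0, so no curve was fitted to the processed intensity. The deposited mean and local background intensity of each spot come before those steps and were used only in an alternative. The deposited log10 ratio of each spot is red over green, and outside spots with substituted signals it equalled log10 of the processed signals. The deposited flags, recorded as 0 or 1, mark spots that the scanner software called non-uniform, population outliers, saturated or well above background. The value table deposited by the authors holds 1 log2 ratio per probe and was made with limma, per the submitters' processing notes, whose background correction and normalization are not given in the sources used here. Set against the scanner ratios, that table is on a log2 scale, runs mutant over reference and lies near 0 on autosomes. Its slope was 0.914 to 1.02 over bright probes, and its nullo X medians on the X arm, -2.75 to -2.02, lay nearer 0 than those of the scanner ratios. Neither its scale, its direction nor its centring stayed unknown, only the steps that made it. Its column medians were 0.01 for 168, -0.00 for 175, 0.06 for 114n, 0.06 for 114f, 0.06 for 186n, -0.01 for 186f, 0.07 for B2580 and -0.03 for B5280.

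From the scanner tables, the log2 ratio of red over green processed signal was taken for each spot, control spots and outlier-flagged spots were left out, repeat spots of a probe were averaged, and each array was centred on the median of its autosomal probes. This left 83472 probe names, of which 23447 are gene probes and 60025 carry no position. Among gene probes 23401 have a position on build dm3, per the file headers, and 3730 lie on the X arm, with a median spacing of 2.06 kb. The unplaced probes come in sets whose name prefixes no source used here explains, and almost every one names a contig of its own. Gene and transcript names are those of the array design. No repeat family is named in the files, so the rule for repeat families took none. Release 6 gene symbols were used only to check spelling, and no coordinate was taken from them.

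The labels give 6 genotypes whose embryos lack most of the X (nullo X, replicates 1 to 6 being 168, 175, 114n, 186n, B2580 and B5280) and 2 whose sole X is deficient (fog, replicates 1 and 2 being 114f and 186f). Each genotype is 1 array, so a class mean averages different genotypes and its SD is the spread between them. Nothing in the labels says that DNA came from separate collections, so p-values measure only the spread between these arrays, part of which may be technical. The arrays lie on 5 slides scanned on 3 days. Slides 2 and 3 each hold both classes of a cross, and B2580 and B5280 each have a slide and a scan day of their own.

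Class differences in the median log2 ratio of the X arm, the Y and autosomal heterochromatin were tested by exact two-sided permutation over all 28 splits of the arrays, whose smallest p is 0.0357, with Benjamini-Hochberg adjustment over the 3 tests. Single probes, genes and sequences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) at a Benjamini-Hochberg adjusted p of 0.05. Sequences were the heterochromatin scaffold sets and, on chromosome arms, bins of 100 kb, each with at least 10 probes and averaged over probes. X segments were found in each array by a 2-state hidden Markov model with Gaussian emissions fitted by expectation maximization. It used a transition probability of 1e-06 per probe, values winsorized at 3 robust SDs, segments of at least 20 probes and states at least 1 log2 unit apart, and boundary intervals took log-likelihoods within 3 of the best. An X scaffold or an unplaced probe counted as present where it lay above the midpoint of the retained and absent X levels of its array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

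Loci to be named, tests and alternatives were fixed before the data were examined. The rule took the loci of the labels' genotypes (y, sc, arm, N, w, ct, f, mal, fog and the Bar homeobox genes B-H1 and B-H2), further X loci (nullo, v, Ste, run, shakB, stnB, su(f), flam and the rDNA unit), 6 Y loci, and autosomal loci with the histone unit as controls. It added the nearest named gene on each side of a segment boundary and the 5 sequences at each end of the class difference. Probes of flam, CCY and the rDNA unit were not identified by name and are not analysed here. A short-segment model was added after the data were seen. It fixed the 2 state levels, spread 2% of probes over a range of 12 log2 units as outliers and took segments of at least 5 probes. A correction for probe GC content was also added, which subtracts the median of autosomal gene probes in each bin of 5% GC with at least 20 probes.

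The scripts were tested on simulated data. In 929 simulated sequences, the limma step recovered 96% of shifts by -3 and 82% of shifts by -1, and 4.26% of its calls were unshifted. Over 72217 simulated probes it recovered 80% of shifts by -3, 36% by -1, 24% by 1 and 56% by 3, and 5.77% of its calls were unshifted. The simulated arrays were independent, with the same spread in both classes. In the data the correlation within slides was 0.786 over probes and 0.918 over sequences, so these rates need not hold there. The main segment model found 20 of 20 simulated retained segments of 30 probes, 9 of 20 absent segments of 30 probes and none of 10 probes, and the short-segment model found 20 of 20 at each size. Alternatives were centring on all probes, normexp background correction with an offset of 50, loess, the scanner's log10 ratio, the authors' value table, filters on dim, saturated and flagged spots, slide as a random or fixed block, other model settings, and leaving out each array in turn.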

Results

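The data are 8 array comparative genomic hybridizations of Drosophila X chromosome deficiencies and duplications on an array built for heterochromatin. Males carrying a piece of the X on the Y were crossed to attached-X females, whose 2 X chromosomes travel together, so that some embryos received no free X. Embryos of this nullo X class keep only the X piece carried by the Y and were picked by their failure in cellularization, and for B2580 and B5280 by defects in cellularization or posterior midgut formation. The duplications were Dp(1;Y)y[2]67g in 168, Dp(1;Y)y[2]sc in 175, Dp(1;Y)y[+]mal[126] in 114n, Dp(1;Y)y[+]mal in 186n, Dp(1;Y)ct y[+] in B2580 and Dp(1;Y)ct[+]y[+] in B5280. In crosses 114 and 186 the fathers also carried a deficient X, and embryos with that X as their only X (the fog class, named for folded gastrulation) were picked by posterior midgut defects. These were Df(1)fog[114] in 114f and Df(1)mal12 in 186f. The question posed by the design is how much of the X, and of its heterochromatin, each chromosome carries.

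All values are log2 ratios of mutant over reference DNA, centred on autosomes, on build dm3. Most spots passed the scanner's test for signal well above background on every array. The reference channel was well above background in 95.3% to 98.6% of spots and the mutant channel in 97.3% to 99.1%. Even on the X arm, only 1 of 3730 probes failed that test in the mutant channel on every nullo X array. On single nullo X arrays 99.09% to 99.97% of X arm probes passed it. Since these embryos lack most of the X, the test does not separate present from absent sequence. The share of outlier-flagged spots was 0.708% to 9.87%, highest in 186f, and the probe-to-probe SD was 0.344 to 0.654, highest in B5280. With 1 array per genotype, the number of arrays limits the precision. The labels do not state the sexes of the reference embryos, so ratios were not turned into copies.

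Both fog genotypes read low at the targeted locus. The gene fog encodes a secreted signal for cell shape change in gastrulation. Its mean log2 ratio over 3 probes, 2 of them with reference signal well above background on every array, was -3.87 in 114f and -2.51 in 186f. It read -0.72 in 168, -0.57 in 114n, -0.73 in 186n and -0.91 in B5280, and -3.53 in 175 and -2.93 in B2580. The X arm as a whole had medians of -3.73 in 168, -3.57 in 175, -3.47 in 114n, -3.57 in 186n, -2.46 in B2580 and -2.84 in B5280, against -0.51 in 114f and -0.53 in 186f. Of the loci named in the duplications, y in 168 (-3.89), mal in 114n (-4.02) and ct in B2580 (-2.51) read near the absent level of their array. The labels name an allele of each without stating whether that sequence is carried. By contrast mal read -0.51 in 186n and ct -0.49 in B5280.

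Nullo X embryos had lost most of the X arm relative to fog embryos. The class mean was -3.27 ± 0.50 (SD, n = 6) against -0.52 ± 0.0087 (SD, n = 2), a difference of -2.75, and all 6 nullo X arrays lay below both fog arrays. The exact two-sided permutation test gave p = 0.0357, the smallest possible over 28 splits, and 0.0536 after adjustment over the 3 class tests. Within the slides that hold both classes, the difference was -2.96 in cross 114 and -3.05 in cross 186. On scan day 1 alone, with 4 nullo X and 2 fog arrays, it was -3.06, where the smallest exact p is 0.0667.

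Y sequences were higher in nullo X embryos, which inherit a Y from each parent. The medians of the 17 probes on Y heterochromatin averaged 1.74 ± 0.07 (SD, n = 6) in the nullo X class and 0.81 ± 0.10 (SD, n = 2) in the fog class. On the linear scale the levels were 3.33 and 1.75 times the reference, a ratio of 1.90 between the classes. The log2 difference of 0.92 had an exact permutation p of 0.0357, adjusted to 0.0536, and held in all 6 arrays. It was 0.97 within cross 114 and 0.80 within cross 186. Taken as means over probes instead, the class levels were 1.54 and 0.78, a smaller log2 difference of 0.75.

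Pooled over its probes, autosomal heterochromatin passed no test between the classes. Its medians averaged 0.05 ± 0.02 (SD, n = 6) in nullo X and 0.04 ± 0.01 (SD, n = 2) in fog embryos, a difference of 0.0098 with an exact permutation p of 0.571. Taken singly and as means over probes, 2L and 3L heterochromatin were higher in nullo X by 0.12 and 0.11 (limma adjusted p = 0.0230 and 0.0183), while as medians over probes they differed by 0.08 and -0.01 (0.731 and 0.905). The autosomal control genes were Adh (alcohol dehydrogenase), bcd (the anterior morphogen bicoid), ci (cubitus interruptus of the hedgehog pathway), lt (light) and rl (rolled, a MAP kinase). Of these 5, 0 passed limma's test over 16168 gene names, and 0 passed when adjusted over the list alone. In B5280, where GC-rich probes read high, Adh read 0.76, bcd 0.39 and ci -0.28. The 23 probes of the histone unit averaged 0.29 ± 0.07 (SD, n = 6) and 0.28 in the classes.

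**Figure D1:**
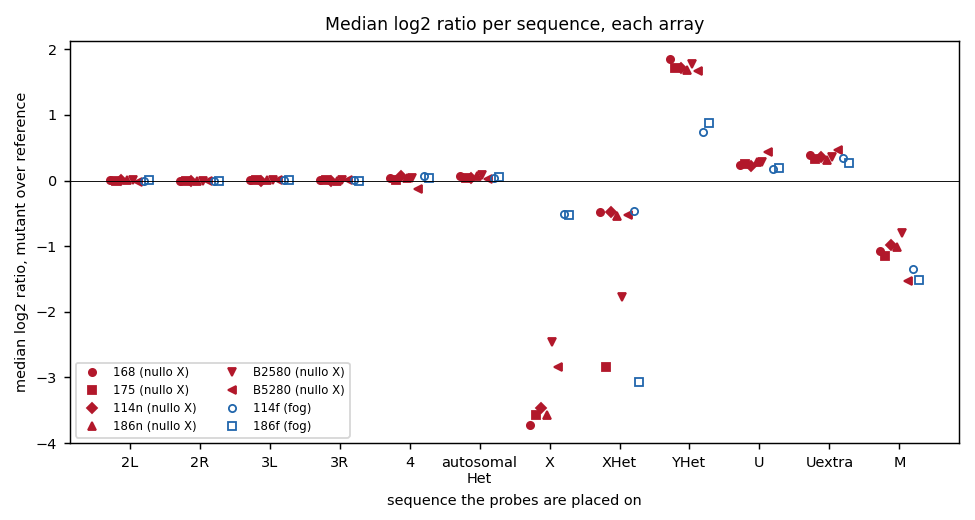
Median log2 ratio of mutant embryo over Oregon R DNA (vertical axis) for the probes of each sequence (horizontal axis), 1 symbol per array, nullo X filled red and fog open blue. X arm medians lie between -3.73 and -2.46 in nullo X arrays and at -0.51 and -0.53 in fog arrays, while Y heterochromatin lies between 1.68 and 1.85 and at 0.74 and 0.88.

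Each Y carried a different piece of the X, and the piece covering the distal tip was the one shared most widely. In 168 the Y carried X 469552 to 970150 (Appl, the amyloid precursor homologue, to CG3655), X 1182628 to 1882971 (CG32812 to TC207207) and X 21848879 to the last probe at 22416921 (CG14621 to CG13865). The profile-likelihood interval for the start of the last piece, 21884452 to 21887264, lay proximal to its first probes. The 29 probes between the distal pieces, X 1028299 to 1145669, had a median of -3.33. The second piece holds arm, which encodes the beta-catenin Armadillo and read -0.91 in 168 and between -3.53 and -2.38 in the other nullo X arrays. The total was 1769 kb. The nearest genes outside were GH17517, A3-3, CG3600 and DIP1.

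In 175 a single piece ran from the first probe at X 20920 to 1185264, from CG17636 to DAAM, a formin, and spanned 1164 kb. The next probe, in TC214044, was absent. The proneural gene sc read -0.42 there and between -3.84 and -2.66 in the other nullo X arrays. No proximal segment of the X arm was retained in 175, and 11 of 17 scored XHet probes were absent there.

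In 114n and 186n the same distal tip was retained, X 20920 to 264859, from CG17636 to the proneural gene ac, with the neighbouring sc probe absent at -3.29 and -3.84. Both also kept X from 19745328, within jog, with the absent probe at 19727593 also in jog. In 186n that piece ran unbroken to 22416921, a length of 2672 kb. In 114n it stopped at 20054471 in CG9576, was missing for 1211 kb from CG9577 to CG1678, and resumed at 21295618. Loci inside the gap separated the arrays. The gene mal, for a molybdenum cofactor sulfurase, read -4.02 in 114n and -0.51 in 186n, and run, the pair-rule gene runt, read -3.64 and -0.57. Retained lengths were 1674 kb in 114n and 2916 kb in 186n.

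In B2580 the tip was the sole piece, 243.9 kb, and in B5280 it came with 2 others. These were X 6844761 to 7790757 (CG4575 to p115, 946.0 kb) and X 19852533 to 22416921 (CG12655 to CG13865, 2564 kb), for a total of 3754 kb. The former holds ct, the homeobox gene cut, and nullo, which is needed for cellularization. They read -0.49 and -0.29 in B5280, against -2.51 and -3.03 in B2580. The 9 outermost probes of the tip, X 20920 to 39560, were low in both arrays (-2.56 in B2580 and -3.69 in B5280), and the short-segment model, added after the data were seen, began the tip at 84605 in SP71. The boundary interval for the proximal end of the B5280 tip, 20920 to 22076, did not contain that end. At a transition probability of 1e-09 the main model did not call the B5280 tip, and 3510 kb were retained there. The retained tip read 0.23 in B2580 over its 21 probes and between -0.66 and -0.53 in the other 4 nullo X arrays that retain it. Outside the tip the X level of B2580 was 0.181 of the reference, against 0.069 to 0.119 in the other nullo X arrays.

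**Figure D2:**
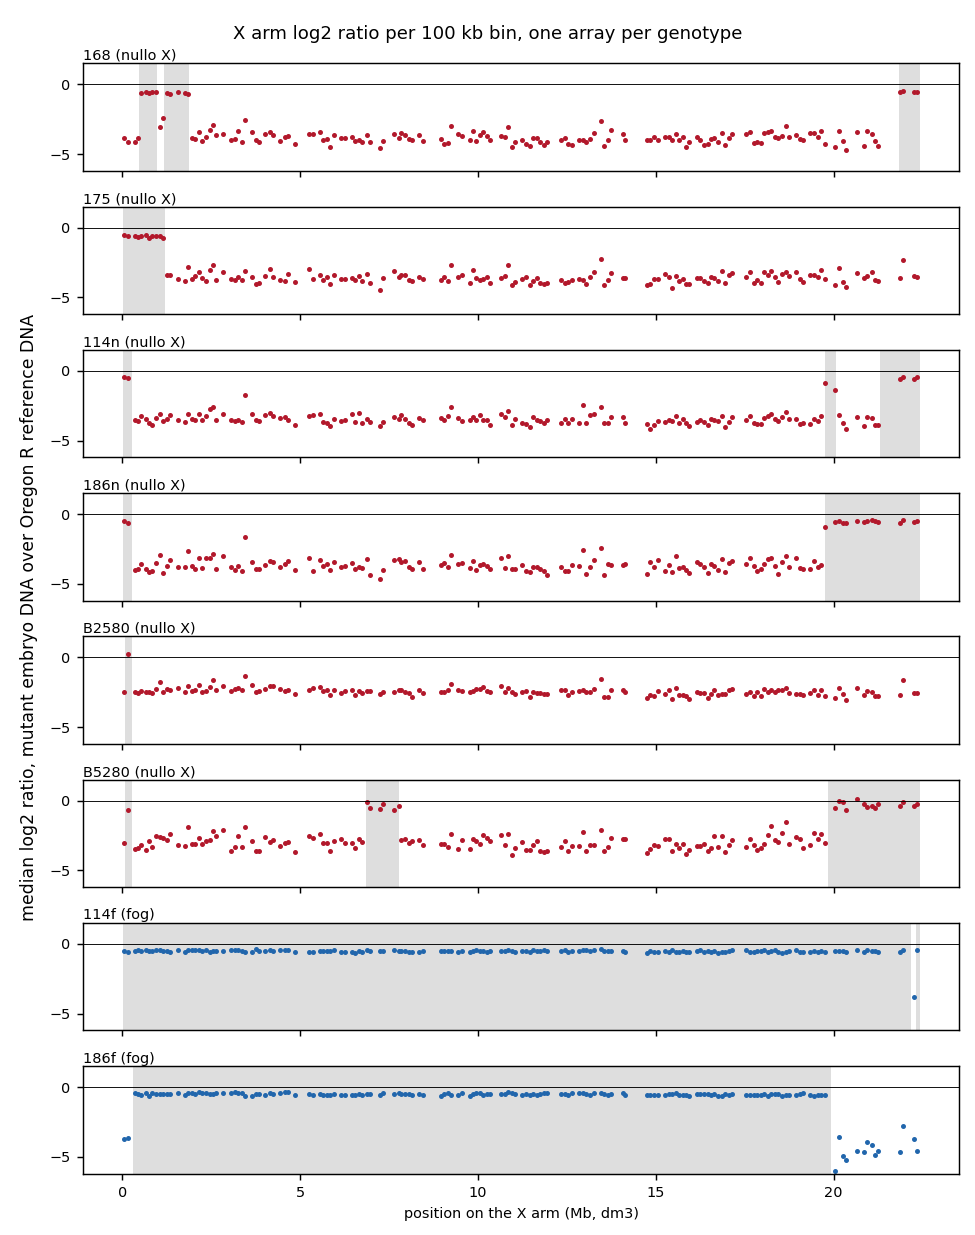
Median log2 ratio in each 100 kb bin (vertical axis) along the X arm (horizontal axis, Mb on dm3), 1 panel per array, with retained segments shaded. The 13 retained segments of the nullo X arrays stand above absent stretches, and 186f shows absent sequence at both ends of the arm.

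In the fog class, the deficient X of 186f lacked sequence at both ends, and that of 114f lacked a small block around fog. The 186f deletions were X 20920 to 291357 (CG17636 to sc, 270.4 kb) and X 19946496 to 22416921 (CG9570 to CG13865, 2470 kb), flanked by l(1)sc and by the dopamine receptor gene D2R. With loess, the scanner's log ratio, the authors' table or the filter on reference signal, the distal deletion ended at 264859 in ac and left out sc, for 2714 kb in all. In the 186f deletions y read -3.51, mal -4.91 and run -4.66, whereas in 114f these read -0.30, -0.71 and -0.62. The sc probe, whose reference signal was not well above background on every array, read -1.56 in 186f. For 114f the main model, whose self-test missed such short absent segments, called none. The short-segment model therefore took the absent level and spread for 114f from 186f. The short-segment model called 15 probes at X 22181094 to 22319288 (138.2 kb, FBtr0111184 to FBtr0111195) absent with a median of -3.80, between CG41476 and FBtr0111185, a stretch that includes CG12446, fog and CG34334.

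Nearly all of the sequence missing from a fog embryo was carried by the nullo X embryo of the same cross. In cross 186, 2714 kb of the 2741 kb deleted in 186f were retained in 186n, which is 99.0%. In cross 114 the main model gave an overlap of 0 kb, and the short-segment model placed all 138.2 kb of the 114f deletion inside a piece retained in 114n. Over 165 sequences, which are 164 bins of 100 kb and the XHet scaffold set, the nullo X array was lower by more than 1 log2 unit in 156 and higher in 1 in cross 114, and lower in 147 and higher in 17 in cross 186. Single bins were not tested within these 2 pairs.

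**Figure D3:**
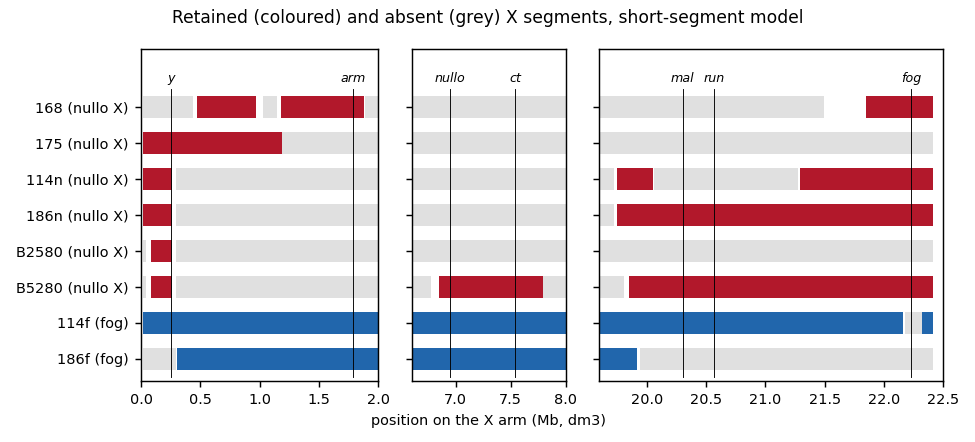
Retained (coloured) and absent (grey) X segments by the short-segment model for each array, along both ends and the region around ct on the X arm (horizontal axis, Mb on dm3), with named loci as vertical lines; white gaps lie between the flanking probes. The blue bar of 114f breaks only at fog, at 22181094 to 22319288, and this gap lies within the red bar of 114n.

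Probe by probe, the class difference fell on the X arm, on Y heterochromatin, on sequence with no chromosomal position and on a few probes of autosomal heterochromatin. Of 83376 probes tested with limma, 3363 were lower and 1646 higher in nullo X at an adjusted p under 0.05. On the X arm 2197 of 3726 were lower, and on Y heterochromatin 11 of 17 were higher. The unplaced sets took up most other calls, with 983 lower and 62 higher in the contig set, 121 and 675 in the R set, and 39 and 725 in the nw set. The sets U and Uextra added 53 and 32 higher probes. On the large autosome arms calls were few, with 5 lower and 2 higher on 2L, 4 and 4 on 2R, 2 and 4 on 3L and 2 and 3 on 3R. Autosomal heterochromatin had 0 lower, and higher were 2 of 37 probes on 2LHet, 5 of 105 on 3LHet, 2 of 89 on 3RHet and 2 of 124 on 2RHet. Counts depend on the 2 fog arrays: without fog replicate 1 they were 732 lower and 1172 higher, and without fog replicate 2, 773 and 994. Without nullo X replicate 6 there were 3951 and 2593, and with slide as a fixed block 2918 and 1279.

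Averaged over sequences, 129 of 929 were lower in nullo X and 4 higher. The lower ones were 128 of 164 X bins and 1 bin on 2L. The strongest were X bins starting at 15900001 (-3.32 ± 0.38, SE), 13000001 (-3.28 ± 0.42), 15400001 (-3.26 ± 0.35), 10900001 (-3.22 ± 0.41) and 5800001 (-3.20 ± 0.43), each with a limma adjusted p of 0.00223. The 2L bin at 5300001 differed by -0.26 and owes this to 1 probe of cype, a cytochrome c oxidase subunit gene, which read -3.90 in nullo X and -0.46 in fog. The 4 higher sequences were Y heterochromatin (0.75 ± 0.06, SE, adjusted p = 0.00223), the unplaced set U (0.39 ± 0.07, 0.00676), 2L heterochromatin (0.12 ± 0.03, 0.0230) and 3L heterochromatin (0.11 ± 0.02, 0.0183), where 5 of 105 probes were called higher. Counting the main setting, the Y call was made under 22 of 22 settings, that of U under 21 of 23, that of 3L heterochromatin under 14 and that of 2L heterochromatin under 11. With medians over probes the Y call alone was made. This count was 2 without nullo X replicate 1, fog replicate 2 or nullo X replicate 5, 7 without fog replicate 1, 8 without nullo X replicate 6 and 19 with slide as a random block.

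Among the X loci of the genotypes, 4 of 11 measured genes were lower in nullo X over all gene names, 7 when adjusted over the list alone, and 0 were higher. These 4 were the Bar homeobox genes B-H1 (-4.49 ± 0.59, SE, limma adjusted p = 0.00265) and B-H2 (-3.86 ± 0.46, 0.00254), the receptor gene N, or Notch (-2.73 ± 0.45, 0.00506), and f, or forked (-1.75 ± 0.42, 0.0343). The list alone added arm (0.0375), ct (0.0375) and w, the white pigment transporter gene (0.0240). The remaining y, sc, mal and fog lie in pieces retained by some nullo X genotypes, as do arm and ct. Unlike arm and ct, these also read low in the fog class. In 186f y read -3.51, sc -1.56, mal -4.91 and fog -2.51, and in 114f fog read -3.87. The call for f was lost without any of nullo X replicates 1 to 4 or either fog array (adjusted p 0.0578 to 0.299) and that for N without fog replicate 2 (0.0547). Calls were gained for arm without nullo X replicate 1 (0.00603), for sc without nullo X replicate 2 (0.0122), for ct without nullo X replicate 6 (0.00640) and for w without nullo X replicate 5 or 6 (0.0330 and 0.0353). Blocking on the slide also brought ct and w past the threshold, with adjusted p = 0.00113 and 0.000336 for a random block and 0.00257 and 0.00127 for a fixed block, as did scan day 1 alone (3.56e-05 and 1.18e-05), and w also passed after GC correction (0.0116). Scan day 1 and a fixed slide block draw on neither B2580 nor B5280, so both settings overlap with leaving those arrays out.

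Of 9 measured further X loci, 1 was lower over all gene names and over the list alone, v or vermilion, an eye pigment enzyme gene (-1.96 ± 0.35, SE, limma adjusted p = 0.00728; 0.0513 and 0.0818 without fog replicate 1 or 2). The gene nullo differed by -2.80 with an adjusted p of 0.341, which became 0.00645 without B5280, the array that retains it, 0.00266 and 0.00157 with slide as a random or fixed block and 9.23e-06 on scan day 1 alone. Neither scan day 1 nor a fixed slide block draws on B5280, which has a slide and scan day of its own. The neuronal gene shakB and the pattern gene run differed by 0.21 and 0.08 and did not pass. The neuronal gene stnB differed by -0.72, with 114f as its only fog value. Its probe lies within the stretch called deleted in 186f. The fog arrays lay far apart for shakB (-0.38 in 114f, -2.46 in 186f) and run (-0.62, -4.66). The direction of both differences therefore turned on which fog array was used. Of 3 Stellate genes, with 1 probe each and repeats on the X, none passed. CG33240 averaged -2.38 in nullo X, against -0.00 in 114f and -3.11 in 186f. CG33246 averaged -2.71, against 0.16 and -3.26, so for both genes the direction turned on the fog array. Of 5 measured Y loci, 4 were higher over all gene names and over the list alone. They were kl-3 (0.85 ± 0.07, SE, limma adjusted p = 0.00162), kl-2 (0.98 ± 0.09, 0.00188) and kl-5 (0.87 ± 0.15, 0.00593), which encode dynein heavy chains of the sperm tail, and Ppr-Y (0.82 ± 0.10, 0.00254). Ory differed by 0.67 (0.574) and read 2.96 in B2580, with fog values far apart at 0.93 in 114f and 2.02 in 186f. The call for kl-5 was lost without fog replicate 1 (0.0647) or 2 (0.0504) and with slide as a fixed block (adjusted p = 0.109).

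The X heterochromatin of the XHet set, with probes at 6928 to 191757, was retained by 4 of the 6 duplications. Other X heterochromatin was not scored in this way. The 20 probes of the XHet set had medians of -0.49 in 168, -0.48 in 114n, -0.54 in 186n and -0.52 in B5280, near the retained X level of each array. They read -2.85 in 175 and -1.78 in B2580, although 6 of 17 scored XHet probes read present on all 8 arrays. Among the fog arrays they read -0.46 in 114f and -3.07 in 186f. The gene su(f), an mRNA 3' end processing factor placed in XHet at 77844 to 79939, followed the same order, at -3.82 in 175, -3.88 in 186f and -2.33 in B2580 and between -0.48 and 0.50 elsewhere. No unplaced contig reached 10 probes, so the planned ordering of contigs could rest on XHet alone.

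Some single unplaced probes, scored after the data were seen, shared the presence patterns of placed X sequence. Of 46882 scored, 8865 were absent on at least 1 array, against 61 of 15859 probes on autosome arms. The pattern of XHet, absent in 175, 186f and B2580 and present in the other 5 arrays, was shown by 1217 unplaced probes, by 11 of 17 XHet probes and by no autosomal probe. It was also shown by 39 X arm probes. The 287 unplaced probes absent in 168, 175, 186f and B2580 shared their pattern with 23 X arm probes. The pattern of the X arm, absent in all 6 nullo X arrays and present in both fog arrays, was shown by 946, and by 1833 X arm probes. Other patterns matched little or no placed X sequence, such as the 628 probes absent in 186f alone, the 399 absent on all 8 arrays, the 329 absent in 175 and 186f and the 324 present in 114f alone. For 114f the absent level behind these calls was that of 186f. The 1400 absent in B2580 alone exceed the 121.2 given by the autosomal rate, although 41 autosomal probes read the same way. The absent cut of B2580 was -1.15, against -2.36 to -1.76 on the other arrays, since its retained level came from the tip alone. With it 0.315% of scored autosomal probes read absent, against 0.032% to 0.069% elsewhere. On U and Uextra, TC213063 and CR41610 were called absent in 175 and 186f and read -1.13 and -1.06 in B2580, just above its cut. The 329 probes absent in 175 and 186f may thus not be apart from the XHet pattern.

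Some genes on the unplaced sets U and Uextra differed between the classes. Higher in nullo X by limma were 59 of 173 U genes and 33 of 136 Uextra genes, and lower were 2 and 4, while 112 and 99 did not pass. The genes CG41038, CG32641, TC211120 and CG33222 were absent in all nullo X arrays and present in fog arrays, with class differences of -4.14, -4.16, -3.29 and -3.01. CG40794, CG40813, CG41562, TC217381 and CG41545 were absent in 168, 175, 186f and B2580, and in 168 read between -5.36 and -2.67. Among the higher genes were CG40534 (1.38 ± 0.08, SE), CG41564 (1.39 ± 0.08) and TC215199 (1.40 ± 0.08), each with a limma adjusted p of 0.000476. These gene names were chosen after their values were seen.

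**Figure D4:**
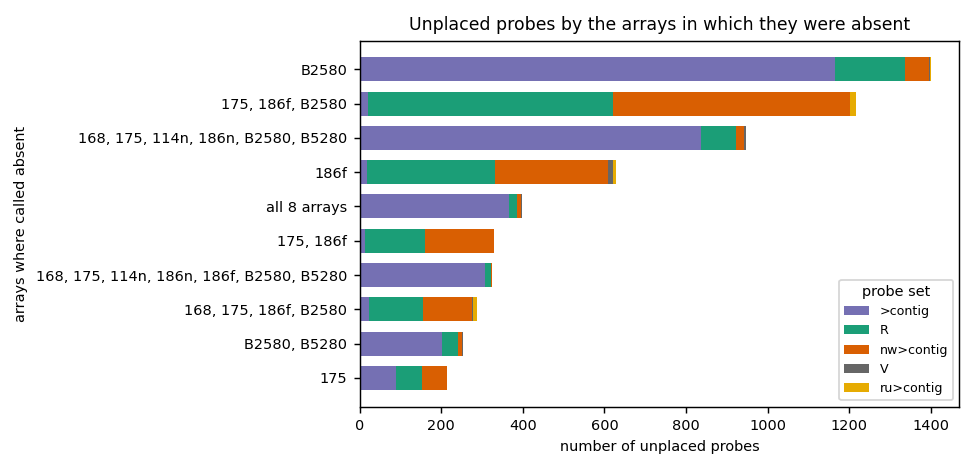
Number of unplaced probes (horizontal axis) absent in each set of arrays (vertical axis), stacked by the prefix of the probe name, for the 10 most frequent sets. The set of 175, 186f and B2580 holds 1217 probes, and that of all 6 nullo X arrays without the fog arrays holds 946.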

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

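Every test that weighs an explanation here was chosen only after the result was seen. In 37 groups of arrays compared for a sample far from the rest, 7 had one, and chance gives about 1 in 20. The difference between crosses was not tested.

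In single arrays, 4 further values stood apart from the other nullo X genotypes. The gene sc read -0.42 in 175, where the nearest other array was -2.66, and it lies in the piece called retained in 175. The y probe read -3.89 in 168, although the label names a y allele, where the nearest was -0.74, and it lies in the 70 probes at X 20920 to 436876 called absent in 168. The Y gene Ory read 2.96 in B2580, where the nearest was 2.07. The gene ci on the 4th chromosome read -0.28 in B5280, where the nearest was -0.07. All 234 probes of that chromosome had a median of -0.13 in B5280, against 0.01 to 0.07 on the other arrays. Between the crosses, 9 bins of 100 kb at X 20102570 to 21299779 were lower in 114n than in 114f and higher in 186n than in 186f, each by more than 1 log2 unit.

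B5280 stood above the other nullo X arrays for the unplaced set U (0.43, nearest 0.29), Adh (0.76, nearest 0.05) and bcd (0.39, nearest -0.00), and 10904 of 54111 unplaced probes were raised there by more than 1 log2 unit, with a median GC content of 55%. The GC content of the probes may account for the rise, since 694 autosomal gene probes of at least 50% GC were raised by 1.38 (0.89 to 1.85) and 12351 unplaced ones by 1.06. At matched GC content this rise over the other 5 nullo X arrays was smaller in unplaced than in autosomal gene probes, by -0.49 (-0.99 to -0.11 over GC bins). In B5280 itself the unplaced probes of at least 55% GC read 1.81 and the autosomal ones 1.60, while at 50% to 55% GC they read 0.85 and 0.92. On the other 5 arrays those of at least 55% GC read 0.405 to 0.508 and -0.065 to 0.055. After a GC correction 4466 unplaced probes (8.25%) and 765 autosomal ones (4.02%) were still raised. In B2580 they were 6880 (12.7%) and 25 (0.13%). In 168, 175, 114n and 186n the shares were 2.29% to 3.97% of unplaced and 0.03% to 0.11% of autosomal probes. More copies of some repeats in B5280 thus cannot be told apart from a GC effect that the correction missed. Why this array alone follows GC stays open, since its slide and scan day are its own.

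The X arm of B2580 kept a level of 0.181 of the reference where it should be absent. Additive background is argued against, because the excess over 4 nullo X arrays in the brightest quartile was 1.05 times that in the dimmest (95% interval 0.994 to 1.12), where background predicts 0.241. Compressed ratios on this array are argued against too, because its Y level of 1.78 lay within the 1.68 to 1.85 of the others, where the same compression predicts 1.16. Embryos with an X in the pool remain a candidate explanation. In 100% of 130 X bins B2580 exceeded the mean of the 4 nullo X arrays, by a shared linear excess with a median of 0.097. B5280 was not among those 4. It read 0.402 in the brightest quartile, against 0.306 in B2580, and 0.084 in the dimmest, against 0.161. A slide and scan day of its own leave other differences of this array open.

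The retained tip of B2580, X 84605 to 264859, read 0.23 over 21 probes, or 1.17 of the reference (interquartile range 1.12 to 1.24). X-bearing embryos alone are argued against, because they allow at most 0.865. Probes that read high anywhere are argued against, because the same probes had a median of -0.56 in 3 other arrays that retain the tip and reached 0.10 at most. The possibility of 2 copies of the tip per embryo predicts a ratio near 2 to those arrays, and the ratio was 1.73 (95% bootstrap interval 1.63 to 1.83). With a single array and an unknown share of X-bearing embryos, 2 copies and a smaller gain cannot be told apart.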

How the results depend on the processing

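The short-segment model, the GC correction, the use of scan day 1 alone and the scoring of single unplaced probes were chosen after seeing the data. Replicate numbers only follow the order of deposit and pair no arrays, so pairing went by the slide that both classes share in crosses 114 and 186, as a block and as within-slide differences. No called result reversed direction, while the autosomal heterochromatin difference, called under no setting, turned negative when centred on all probes, after GC correction and in the authors' table. Of the named genes' values under alternatives, 552 kept their size and side of the threshold, 16 moved, 18 passed it and 12 failed it. The cause was not tested unless stated. Leaving out each array in turn gave X arm differences of -2.92 to -2.66, Y differences of 0.857 to 0.992 and autosomal heterochromatin differences of 0.00 to 0.02, with 732 to 3951 probes lower, 994 to 2593 higher, 120 to 138 sequences lower and 2 to 8 higher. The lowest counts of lower probes, 732 and 773, came without fog replicate 1 and 2, the 994 without fog replicate 2, and 2593 without nullo X replicate 6. With all 8 arrays the X and Y tests each gave an exact permutation p of 0.0357, adjusted to 0.0536, so they passed 0.05 only before adjustment. Without 1 fog array too few splits remain for either test to pass 0.05 even before adjustment. On scan day 1 alone the differences were -3.06 on the X arm and 0.93 on the Y, and its 15 splits cannot pass either. Within cross 186 the Y difference was 0.80. The nullo X level of the X arm was -2.41 with normexp and -2.48 in the authors' table, against -3.27. Probes higher numbered 2949 with slide as a random block and 2679 on scan day 1. Sequences lower fell to 40 at 25 probes or more, because only 360 were tested. Sequences higher numbered 2 when centred on all probes and in the authors' table, 19 with a random slide block, 8 on scan day 1 and 1 with medians over probes. At 50 probes or more per segment, 7 retained and 1 deleted segments were left, because shorter ones were not allowed. The short-segment model kept 13 retained segments and gave 3 deleted ones, with an overlap of 138.2 kb in cross 114 against 0. At a transition probability of 1e-09, 12 segments were retained, and the tip of B5280 was no longer called. XHet stayed retained in 4 nullo X arrays under every setting that gave a value, and at 25 probes or more it gave none. Signal over background limits dim probes most: 92.6% of probes had a reference signal well above background on all arrays.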

Other observations

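The regions and probes here were chosen after their values were seen, and no test was planned for them. Some X sequence read higher in 186f, whose chromosome is an inversion that carries Bar, than in 114f. The 9 probes from B-H1 to CG12432 at X 17297215 to 17426920 had a median of 0.34 in 186f and -0.47 in 114f, with differences per probe between 0.65 and 1.07. The B-H2 probe, distal to them at X 17217925, read -0.46 in 186f and -0.47 in 114f. The 5 probes from CG13373 to CG18166 at X 372140 to 374305 had a median of 0.94 in 186f and -0.47 in 114f, with differences between 1.07 and 1.80. The 4 probes at X 13942256 to 13952560, those of 3 Stellate genes and 1 of FBtr0073882, ran the other way, at -2.53 in 186f and 0.15 in 114f. On autosomes, 9 probes at 2L 5201257 to 5215344, from FBtr0300471 to CG14034, read 0.58 in 186n and 0.68 in 186f and between -0.06 and 0.12 in the other 6 arrays.

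A few probes placed on autosomes followed a sex chromosome. Of 19015 scored, 3 probes of 2 genes followed the X pattern, 2 of the 3 probes of CG10039 and 1 of the 3 of cype, and 15 probes of 14 genes were higher in nullo X like the Y. Ssl averaged 2.32 ± 0.09 (SD, n = 6) in nullo X and 1.13 in fog embryos, with a limma adjusted p of 0.00135. Mst77F, which encodes a sperm chromatin protein, averaged 2.01 and 0.91 (0.0148), with nullo X values from 175, B2580 and B5280 only. CG41344 averaged 2.38 and 0.71 (0.00135), and CG40138 2.42 and 1.16, with 114f as its only fog value. CG42200 had 2 probes that averaged 1.24 and 1.15 in nullo X and 0.42 and 0.28 in fog.

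Mitochondrial probes, 29 in number, lay below the autosomes on every array, at -1.07 in 168, -1.15 in 175, -0.98 in 114n, -1.34 in 114f, -1.01 in 186n, -1.51 in 186f, -0.80 in B2580 and -1.54 in B5280. The embryo ages of the mutant and reference pools differ. The unplaced gene CG41534 read 4.94 ± 0.69 (SD, n = 6) in nullo X and -0.40 in fog embryos, but its reference signal was not well above background on every array.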
